A study of Caenorhabditis elegans with 4 samples.

How the data were processed

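The series comprised 4 samples of C. elegans OP37 at the L4 stage, grown at 20 °C on E. coli and crosslinked with 2% formaldehyde, per the labels' protocols. They were 2 PHA-4 ChIP samples and 2 Input samples, grouped by their titles. After sonication, a part of each lysate was kept as Input and the rest was immunoprecipitated with anti-GFP antibodies, per the labels' protocols. Peak lists were used for both ChIP samples and for the series as a whole, and the Input samples were not analysed here beyond their labels.

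The combined list gives each peak a q-value that the authors computed with PeakSeq, per the file headers. It is 1 list for both replicates, and how they were combined is not given in the sources used here. Its comment lines record that coordinates had been lifted over to WS220 from a build they do not name. Of the peaks, 4 were also listed in those comments. The replicate lists carry a deposited score for each peak and name their caller spp_via_IDR, per the file headers, a name that joins those of the caller SPP and of the IDR method. The files do not say what the score measures. It is capped, and 10 to the power of its maximum is a whole number, 9137 in replicate 1 and 9229 in replicate 2. It was therefore used to rank peaks within a list, with ties ordered by the peak number in the deposited names. The 1 exception is Pearson's r between replicates, which was computed on the log10 of the score. All 3 lists name WS220 as their build. The aligner, the software versions, the thresholds and the use made of the Input reads are not given in the sources used here. A calling threshold acts on every count below: the replicate lists are longer than the combined list and hold peaks of lower rank, so counts of peaks are compared between lists at the same length of 3890 where the comparison allows.

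No read counts come with the lists, so depth per sample is unknown. Precision is given as exact Clopper-Pearson 95% intervals over peaks, which treat peaks as independent, although neighbouring peaks are not. The binomial, chi-square and Fisher p-values rest on the same assumption. No interval was identical in the 2 replicate lists. Replicate 2 held 1 repeated row.

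Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 shuffles of peaks within their chromosomes, with one-sided permutation p-values. Score agreement was computed over the best overlapping pairs with 100000 permutations, two-sided. Chromosome counts were tested by exact binomial tests, two-sided and adjusted by the Benjamini-Hochberg method, and by a chi-square test. Chromosome lengths were taken as the largest coordinate in the lists. The central 33.3% of each autosome was tested by an exact binomial test, and the gaps between neighbouring midpoints by 1000 shuffles, one-sided. Counts of peaks per chromosome were made on 6 nuclear chromosomes. Mitochondrial peaks entered the list totals, the ranking, the replicate overlap, the score agreement and the shares by rank found in the combined list. They are otherwise described separately. With 1 group that has peak lists and 2 libraries in it, no test between groups was made.

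The named peaks followed a rule set before the data were examined, as were the tests above and most alternatives. It took the 20 combined peaks with the lowest q and the 5 highest-ranked peaks of each replicate list that the other list did not overlap, by position where no annotation could be used. Shares by rank, width class and chromosome, clusters, the block on chromosome V and the recovery of replicate peaks by chromosome were added after the data were seen. The planned analyses of gene starts, gene lists, noncoding genes, the PHA-4 motif and the pha-4 and unc-119 loci were not run. They need a genome or gene positions in WS220, and the gene table at hand was of the WBcel235 assembly, so the gene lists fixed beforehand gave no result.

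The scripts were tested on simulated data. For replicate overlap over 19130 peaks, planted sharing of 0%, 25% and 50% was recovered as -0.41%, 24.5% and 49.9%. For chromosome counts over 3890 peaks, 5.5% of 200 draws with no effect gave a call, and a planted 1.2-fold excess on V was called in 99.5% of draws. For spacing over 3890 peaks, a planted 20% of close gaps was recovered as 19.3%. For the chromosome centre over 3235 peaks with no effect, the share was 33.8% (exact p = 0.538). For correlations over 2000 pairs, a planted 0.5 was recovered as 0.49. Alternatives were a reciprocal overlap of 50%, peak points within 200 bp, higher-ranked peaks alone, lists limited to 3890 peaks, each replicate's own list in place of the combined one, a central 50% of chromosomes, joining of near peaks, local shuffles within 50 kb, and leaving out mitochondrial peaks or the block on V. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.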

Results

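Binding of PHA-4, the FoxA transcription factor required for formation of the pharynx, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans. The animals were fourth-stage (L4) hermaphrodites of the strain OP37, in which a pha-4 transgene tagged with green fluorescent protein had been introduced by bombardment together with an unc-119 rescue gene. Chromatin was immunoprecipitated with antibodies against the fluorescent tag. The series held 2 PHA-4 ChIP libraries and 2 Input libraries of total chromatin DNA. Each ChIP library had a peak list of its own, and a further list, called here the combined list, stood for the series as a whole. The Input libraries had no peak list, so no comparison with Input was made here. Whether the authors' q-values and scores were set against Input is not given in the sources used here. The lists give no read counts, so the sequencing depth of each library is unknown. Intervals below are exact (Clopper-Pearson) 95% intervals over peaks and cover counting error only. Nothing in the labels states that the 2 ChIP libraries came from separate cultures, so the spread between them may be technical.

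The first question was how many regions PHA-4 occupied and how large they were. The combined list held 3890 peaks with a median width of 382 bp (interquartile range 305 to 540 bp), which covered 1910.4 kb, or 1.91% of the nuclear genome. Widths ran from 25 to 9487 bp, and 224 peaks (5.76%) were wider than 1 kb. The q-values that the authors' caller gave these peaks ran from 2.91e-198 to 0.00995, with a median of 0.000389. The replicate lists were longer and of nearly uniform width. Replicate 1 had 19158 peaks, of which 99.8% were 316 bp wide, and replicate 2 had 19505, of which 99.8% were 320 bp wide. They covered 5.94% and 6.12% of the nuclear genome. The score that the authors gave each replicate peak was capped: 4569 peaks (23.8%) of replicate 1 shared the maximum of 3.96, and 4615 (23.7%) of replicate 2 shared the maximum of 3.97. Within the capped peaks the order was taken from the deposited peak number. The 3890 highest-ranked peaks of each list, compared below, were all capped, so their selection among capped peaks rests on that number alone.

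The second question was how far the replicates found the same regions. Of the replicate 1 peaks, 9204 (48.0%, interval 47.3% to 48.8%) were overlapped by at least 1 bp of a replicate 2 peak, against a mean of 11.9% when the peaks were shuffled within their chromosomes, a 4.03-fold excess. In the other direction the share was 47.1% (46.4% to 47.8%) against 11.7%, a 4.02-fold excess. Both had a one-sided permutation p of 0.000999, the smallest that 1000 shuffles can give. Overlap was nearly complete among the highest-ranked peaks and fell along the lists. It was 99% for the first 100 peaks of replicate 1 and 98% for those of replicate 2. It was 81.3% and 81.0% for ranks 2001 to 4000, and 22.6% and 22.1% from rank 16001 to the end. Among the 3890 highest-ranked peaks of each list, as many as the combined list holds, 57.9% of replicate 1 peaks and 57.8% of replicate 2 peaks were shared, which was 19.9 and 19.8 times the shuffled share.

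**Figure D1:**
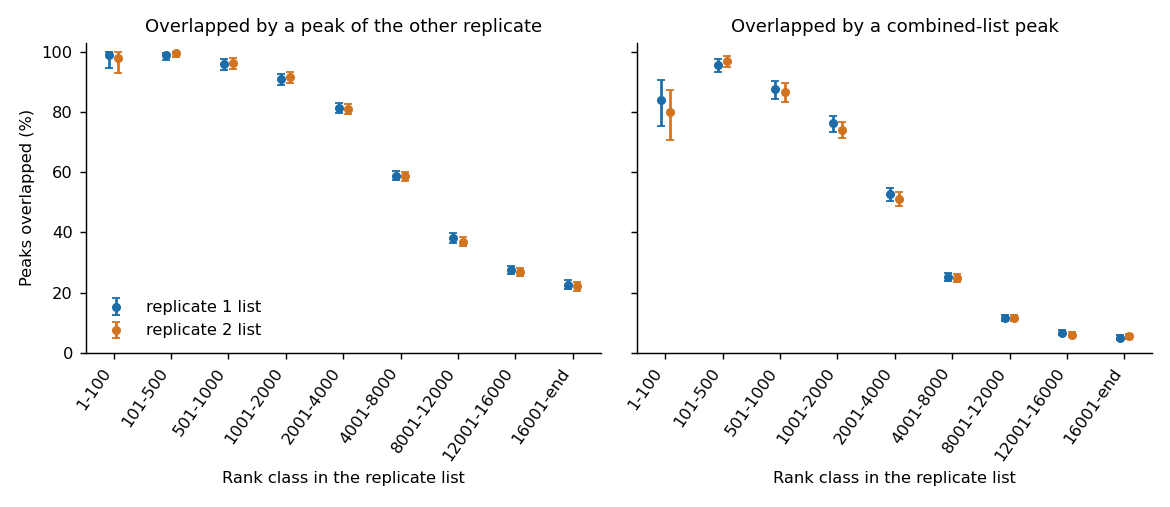
Share of replicate peaks (vertical axis, %) overlapped by at least 1 bp of a peak of the other replicate (left) or of the combined list (right), by rank class in the replicate list (horizontal axis), with exact 95% intervals as bars. For replicate 1 the share found in the other replicate falls from 99% in the first 100 peaks to 22.6% in the last class, and the share found in the combined list is 84% in the first class, 95.8% in the next and 5.07% in the last. The 16 peaks of the first class not found there were mitochondrial, and the combined list holds no mitochondrial peaks.

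The highest-ranked peaks that the other replicate lacked were mitochondrial in both lists, followed by peaks on I, V and X. In replicate 1 the 5 highest were at MtDNA 9923 to 10084 (rank 26), X 7100307 to 7100622 (rank 226), V 8445684 to 8445999 (rank 256), X 4113653 to 4113968 (rank 320) and V 5065211 to 5065526 (rank 366). In replicate 2 they were at MtDNA 5026 to 5410 (rank 21), MtDNA 805 to 934 (rank 62), I 6314765 to 6315084 (rank 298), X 2591805 to 2592124 (rank 331) and I 5372803 to 5373122 (rank 504). All of the nuclear peaks named here overlapped a combined peak. Here and throughout, coordinates are those of the WormBase WS220 build. No annotation of that build was used, so regions are given by position and not by gene.

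Scores of overlapping replicate peaks rose together. Over 8614 overlapping pairs, Pearson's r of the log10 score was 0.35 and Spearman's rho was 0.44. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. This is a correlation across peaks within 1 pair of libraries, and peaks are not independent replicates. In 2633 pairs (30.6%) both peaks stood at the maximum score. With the peak number in place of the score, r, again of log10 values, was 0.63 and rho 0.54. Over the 5121 pairs in the higher-ranked part of both lists (9579 and 9752 peaks), r was 0.22 and rho 0.26 (permutation p = 1e-05 for each). Both peaks stood at the maximum score in 51.4% of these pairs, which limits what the lower values can show.

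The combined list was then set against the replicate lists, to see how much of it each library had found alone. Of its 3890 peaks, 3666 (94.2%) were overlapped by a replicate 1 peak and 3615 (92.9%) by a replicate 2 peak, against shuffled means of 13.9% and 14.2% (one-sided permutation p = 0.000999 for each). A peak of both replicates overlapped 3446 of them (88.6%, 87.5% to 89.6%), and 55 (1.41%) were overlapped by neither. The combined list stands for the same 2 libraries, so overlap above the shuffled means was likely from the start and is not independent support. By chromosome the share found in both was lowest on V, at 78.8% (76.2% to 81.2%), and elsewhere ran from 89.3% on III to 94.8% on I. Fisher's exact test of I against V gave an odds ratio of 4.94 (p = 1.14e-12), in a comparison chosen after the data were seen. The share found in both was 97% for the 100 peaks of lowest q, 93.5% for ranks 1001 to 2000 and 78.1% for ranks 3001 to 3890. The 48 combined peaks wider than 2 kb held on average 4.98 replicate 1 peaks (SD 2.24, n = 48) and 5.04 replicate 2 peaks (SD 2.25, n = 48). Those up to 1 kb wide held 1.08 and 1.07. The count found in both depended on the overlap rule and on the length of the replicate lists: it was 65.0% with overlap of at least 50% of both peaks and 47.04% when each replicate list was limited to its 3890 highest-ranked peaks. The 65.0% is partly set by width. No replicate peak was wider than 423 bp, so none could cover 50% of a combined peak wider than 1 kb. By the 1-bp rule, both replicates had found 47 of the 48 combined peaks over 2 kb and 174 of the 176 of 1 to 2 kb.

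The 20 combined peaks of lowest q lay on all 6 nuclear chromosomes, with 9 on V, 3 each on II, III and IV, and 1 each on I and X. Their median width was 3116.5 bp (723 to 9487 bp), and 19 of them were overlapped by peaks of both replicates. The first was V 20747844 to 20757330, which was 9487 bp wide with q = 2.91e-198 and held 14 peaks of each replicate. The next was V 20772519 to 20779152, 6634 bp wide with q = 5.65e-192, which held the highest-ranked peak of replicate 1 and the second-ranked peak of replicate 2. Both belong to a block near the right end of chromosome V that is described further on, as does V 20761666 to 20762452 (q = 9.63e-43). The other peaks on V were 1803917 to 1806358 (q = 1.41e-129), 14684568 to 14689057 (q = 2.33e-75), 6226827 to 6230084 (q = 2.77e-52), 8934928 to 8938664 (q = 1.82e-44), 13787319 to 13789906 (q = 1.48e-41) and 8383599 to 8386539 (q = 6.46e-36). On X the peak was 16929343 to 16932037 (q = 5.21e-129). Chromosome II had 14404928 to 14408122 (q = 9.94e-106), 5335861 to 5338898 (q = 1.82e-37) and 11756539 to 11757261 (q = 2.01e-34). Chromosome III had 8443501 to 8447247 (q = 7.74e-85), 9050574 to 9055001 (q = 6.89e-78) and 8416927 to 8418042 (q = 3.06e-36). Chromosome IV had 17277722 to 17281659 (q = 1.83e-67), 5604145 to 5605890 (q = 3.88e-41) and 14032498 to 14034765 (q = 5.08e-40). The peak on I, at 15063999 to 15067631 (q = 1.63e-46), was the exception that overlapped no peak of either replicate. The caller's order and that of the replicate lists differed: 3 of the 20 contained a peak from the first 100 of both replicates, and 10 contained a peak from the first 1000 of both. Those 3 were the peaks in the block on V.

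Peaks were next counted per chromosome. In the combined list chromosome V was the densest, with 1055 peaks or 50.5 per Mb, which was 1.30 times the number expected from its length (1.23 to 1.37; adjusted exact p = 4.36e-20). Chromosome III had 681 peaks or 49.4 per Mb, 1.27 times the expected number (1.19 to 1.36; adjusted exact p = 9.59e-11). Chromosome I was the sparsest, with 309 peaks or 20.5 per Mb, 0.528 times the expected number (0.473 to 0.588; adjusted exact p = 5.76e-40), and II had 0.867 times (0.798 to 0.940; adjusted exact p = 0.000581). Chromosomes IV and X did not pass the test, at 0.996 times (adjusted exact p = 0.933) and 0.953 times (adjusted exact p = 0.214). These are two-sided exact binomial tests with Benjamini-Hochberg adjustment over 6 chromosomes. A chi-square test over them gave 255 with 5 degrees of freedom (p = 4.22e-53). With peaks joined within 10 kb it gave 47.9 (chi-square p = 3.76e-09). These tests treat peaks as independent, although neighbouring peaks are not, so their p-values are likely too small.

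The replicate lists gave another order of chromosomes, with III above expectation in each list. Of the 3890 highest-ranked peaks of each, 3863 in replicate 1 and 3862 in replicate 2 were nuclear. Among these, V held 0.705 times the expected number in replicate 1 (adjusted exact p = 7.58e-22) and 0.694 times in replicate 2 (adjusted exact p = 1.36e-23). Chromosome I held 1.06 times (adjusted exact p = 0.0957) and 1.11 times (adjusted exact p = 0.00508), and X held 1.15 times in both (adjusted exact p = 2.76e-05 and 3.03e-05). Chromosome II held 1.114 times (adjusted exact p = 0.00348) and 1.05 times (adjusted exact p = 0.187), and its deficit in the combined list was also lost among peaks found in both replicates (0.920 times, adjusted exact p = 0.0697). Chromosome III held the most for its length in both, at 1.23 and 1.26 times (adjusted exact p = 8.87e-08 and 2.25e-09). The density on V divided by that on I was 2.46 in the combined list, 0.662 (0.590 to 0.743) in replicate 1 and 0.624 (0.557 to 0.700) in replicate 2. In the combined list it fell to 1.58 with peaks joined within 10 kb and to 2.04 among peaks found in both replicates, and was 3.16 among the 1945 peaks of lowest q. Of the highest-ranked replicate 1 peaks on V, 92.4% (89.9% to 94.5%) were overlapped by a combined peak, against 43.2% (39.3% to 47.2%) of those on I. The shares in replicate 2 were 92.3% and 41.4%. Fisher's exact test of I against V gave p = 2.08e-79 for replicate 1 and 2.78e-84 for replicate 2, in a comparison chosen after the data were seen.

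**Figure D2:**
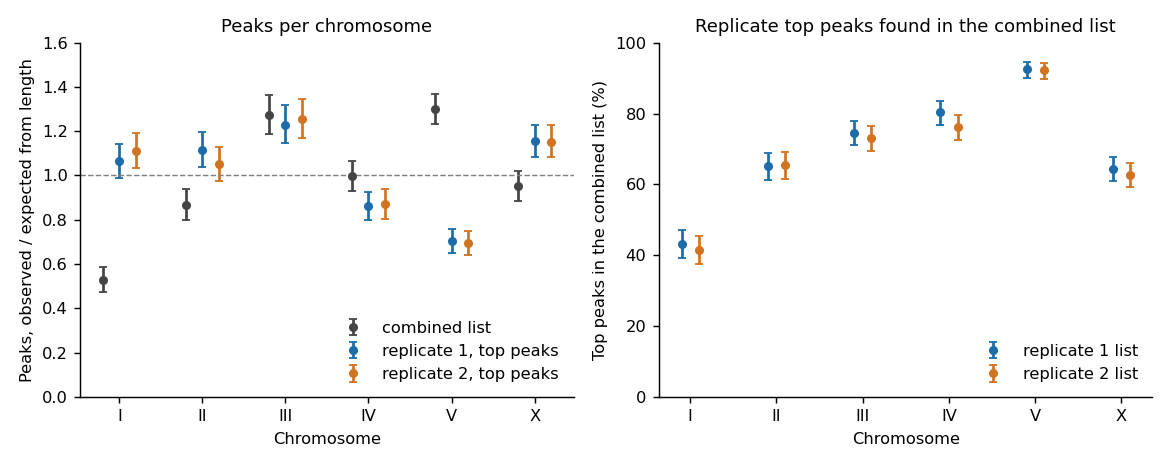
Left, peaks per chromosome as observed over expected from chromosome length (vertical axis), for the combined list and for the nuclear peaks among the 3890 highest-ranked of each replicate list, with the dashed line at equality. Right, share of those replicate peaks overlapped by a combined peak (%). Bars are exact 95% intervals. Chromosome V stands at 1.30 in the combined list and at 0.705 and 0.694 in the replicates, and chromosome I at 0.528 against 1.06 and 1.11.

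Along the autosomes, peaks were denser in the centre than on the arms. In the combined list 1436 of 3235 autosomal peaks (44.4%, 42.7% to 46.1%) had their midpoint in the central 33.3% of their chromosome, a 1.33-fold excess (exact binomial test, p = 7.14e-39). The highest-ranked replicate peaks gave 46.9% and 46.8%. Each autosome showed the excess in the combined list, from 40.5% on III (adjusted exact p = 0.000111) to 49.8% on I (adjusted exact p = 7.09e-09). Chromosome X had the lowest share, 37.9% (34.1% to 41.7%; adjusted exact p = 0.0145). In 1-Mb bins the number of combined peaks ran from 10 at I 14000001 to 15000000 to 105 at V 10000001 to 11000000, with a median of 38 over 97 bins.

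**Figure D3:**
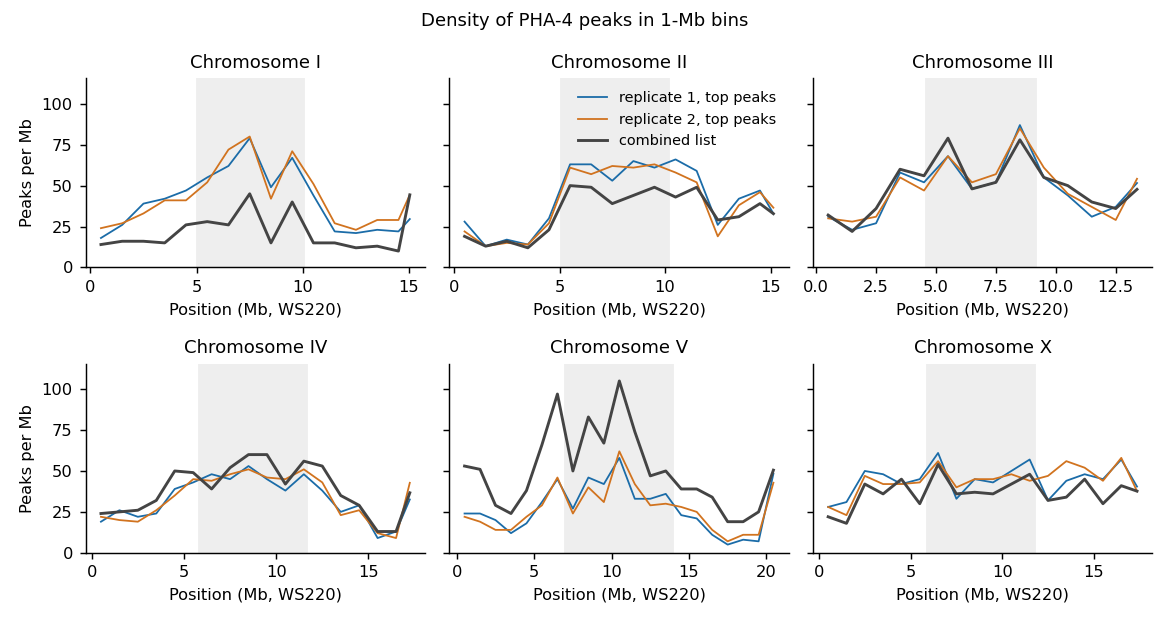
Peaks per Mb (vertical axis) in 1-Mb bins along each chromosome (horizontal axis, Mb), for the combined list and for the 3890 highest-ranked peaks of each replicate list, with the central 33.3% of each chromosome shaded. The combined list reaches 105 on chromosome V, where it lies above both replicates along most of the length, and falls to 10 on chromosome I, where it lies below them except in the last bin, which is short and holds few peaks.

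Neighbouring peaks lay closer together than shuffled ones. Of the gaps between midpoints of neighbouring combined peaks, 35.0% were within 5 kb, against 18.6% after shuffling, a 1.89-fold excess (permutation p = 0.000999, the smallest possible). The median gap was 11602 bp against 17049 bp. Gaps within 1 kb made up 5.20% against 4.04% (permutation p = 0.000999), but this excess was lost when peaks were shuffled within 50 kb of their place, which gave 5.26% (permutation p = 0.572). It was also lost among the 1945 peaks of lowest q, at 2.11% against 2.11% (permutation p = 0.528). Neither loss shows that close clustering was absent. Combined peaks did not overlap one another, so wide ones cannot have midpoints this close, whereas shuffled peaks could overlap. The peaks of lowest q were the widest, with a median of 1351.5 bp for the first 100. Joining peaks closer than 500 bp removes most gaps within 1 kb by construction and left 1.21%, which tests nothing. Among combined peaks found in both replicates the share was 4.24% against 3.53% (permutation p = 0.00699). The highest-ranked replicate peaks gave a larger excess, 8.66% against 3.93% in replicate 1 and 7.13% against 3.92% in replicate 2 (permutation p = 0.000999 for each). This is not a like measure, because several replicate peaks of nearly fixed width can lie within 1 combined peak. With peaks joined where less than 5 kb separated them, 2220 peaks (57.1%) fell into 788 clusters, 73 of which had 5 or more peaks, and 1670 peaks stood alone. The fullest clusters were V 20744248 to 20779152 with 12 peaks, and IV 12196532 to 12209245, V 6220912 to 6234350 and V 10712215 to 10729771 with 11 each. Clusters of 10 were at IV 5586319 to 5607849 and V 10031155 to 10049261.

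The cluster at V 20744248 to 20779152 was also more fully covered than any other window of its length. Over its 34.9 kb it held 12 combined peaks, 43 replicate 1 peaks and 50 replicate 2 peaks, and combined peaks covered 78.5% of it. The highest share in any other window of that length was 35.4%, at II 10523001 to 10557905. Its flanks of the same length were covered at 4.27% on the left and 0% on the right. The block held 6 of the first 50 combined peaks, 6 of the first 100 peaks of replicate 1 and 6 of those of replicate 2. It was defined as the cluster around the combined peak of lowest q, so it holds that peak by construction. By number of peaks it stood out less. A window of that length at V 6213501 to 6248405 held 16 combined peaks, and a window at II 10527001 to 10561905 held 45 replicate 1 peaks, while the highest other count in replicate 2 was 37.

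**Figure D4:**
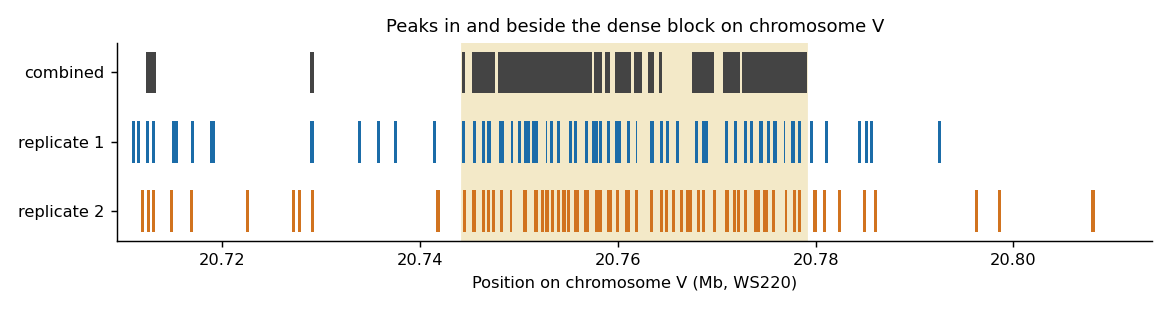
Peaks of the combined list and of each replicate list drawn to scale along chromosome V (horizontal axis, Mb), over the block from 20744248 to 20779152 (shaded) and a flank of the same length on each side. Combined peaks cover 78.5% of the block, 4.27% of the left flank and 0% of the right flank.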

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

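The test of how much of the mitochondrial genome the peaks cover was chosen after the peaks had been seen, and the rotation test was written before its result was known. The replicate lists held peaks on the mitochondrial genome, which none of the comparisons by chromosome, centre or spacing used: 28 in replicate 1 and 30 in replicate 2, against 0 in the combined list. They ranked high, with a median rank of 65 in replicate 1 and 38 in replicate 2, and took 16 and 20 of the first 100 places. The 84 other peaks among the first 100 of replicate 1 and the 80 of replicate 2 were all overlapped by a combined peak. No Input peak list was at hand to set beside them.

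PHA-4 is a nuclear transcription factor, and the design names no biological reason for mitochondrial peaks, so no biological explanation was tested beyond their position. Peaks of the replicates shared more bases than nearly all rotations of replicate 2 gave. They shared 4241 bp, and 0.06% of the rotations shared as many (median 3222 bp). Rotations a few bases apart are nearly alike, so the 0.06% does not rest on independent draws. The circle was 13920 bp, the largest mitochondrial coordinate in the lists, which stands in for the genome's length. So many shared bases are what binding at fixed positions would give. Uneven coverage that recurs between libraries would also give them, and nothing here separates these. Reads from the many copies of the mitochondrial genome may also have been called as peaks, which covered 49.52% of that length in replicate 1 and 46.6% in replicate 2, against 5.94% and 6.12% of the nuclear genome, or 8.33 and 7.62 times the nuclear share. Both values missed what was set for that explanation, over 50% of the length and over 10 times the nuclear share, without reaching the low cover that would argue against it, so it stays open.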

How the results depend on the processing

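The alternatives chosen after seeing the data were local shuffling, leaving out mitochondrial peaks or the block on V, joining peaks within 10 kb, and keeping combined peaks found in both replicates. Over 12 results and 67 alternatives, 48 kept their direction and side of the threshold or stayed within their interval, 12 reversed, 3 moved, and in an unchanged direction 2 passed the threshold newly and 2 no longer passed it. Some that reversed also changed their call, as given below. Replicate overlap exceeded shuffling in each alternative (37.6% to 57.9%), score agreement stayed positive (rho 0.26 to 0.54), and so did the excess in chromosome centres (1.24 to 1.41-fold) and of gaps within 5 kb (1.53 to 2.47-fold). Combined peaks found in both replicates fell from 88.6% to 65.0% with reciprocal overlap and 77.0% with points within 200 bp, as stricter rules must give, and to 47.04% with replicate lists of 3890 peaks. Combined peaks wider than 1 kb could not pass the reciprocal rule, because the replicate peaks were too narrow.

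Chromosome folds depended most on the list. Without replicate 1 or without replicate 2, that is in the 3890 highest-ranked peaks of the other replicate, they were 1.064 to 1.111 on I, 1.05 to 1.114 on II, 0.6938 to 0.7048 on V and 1.153 to 1.154 on X, each on the other side of 1, and 0.8604 to 0.8695 on IV. Here IV and X passed the test in both lists, which they had not in the combined list, while I in replicate 1 (adjusted exact p = 0.0957) and II in replicate 2 (adjusted exact p = 0.187) did not. The full replicate lists lay on the same sides of 1, and there I passed in both (1.058 and 1.076, adjusted exact p = 0.000843 and 1.18e-05), while II in replicate 2 did not (1.028, adjusted exact p = 0.094). Among combined peaks found in both replicates, II was at 0.9198 (adjusted exact p = 0.0697), IV at 1.016 and X at 1.018. With peaks joined within 10 kb, I was at 0.695 (adjusted exact p = 1.04e-08), V at 1.101 (adjusted exact p = 0.0429), II at 0.9449 (adjusted exact p = 0.458) and X at 1.041, and in the 1945 combined peaks of lowest q IV was at 1.031. For II, IV and X the cause was not tested, and I and V are taken up under the contrast between these chromosomes. In these last settings neither IV nor X passed the test. Chromosome III stayed above 1 in each alternative (1.22 to 1.29) and in the full replicate lists (1.175 and 1.177).

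No paired analysis was possible because the Input samples had no peak list here. Replicate peaks have a nearly uniform width, so the peak number replaced width as the other ranking. Other settings for gene starts, gene lists, noncoding genes and the motif, listed before the data were seen, were not run with those analyses. Depth is unknown, so its effect on the number of peaks could not be tested.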

Other observations

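Of the tests in this part, the comparison of chromosomes I and V at matched rank was written before its result was seen, with ranks up to 1000 and beyond 8000 added to it later, and the others were chosen after. The replicate peaks narrower than the fixed width were few and concentrated among the highest ranks. Replicate 1 had 32, of which 26 were among its first 100 peaks, 12 were mitochondrial and 5 lay in the block on V. Replicate 2 had 35, of which 27 were among its first 100, 21 were mitochondrial and 3 lay in the block. The combined peak at I 15063999 to 15067631, which neither replicate list overlapped, reached furthest right of all peaks on chromosome I. Its own end set the length used for that chromosome, so its distance from the true chromosome end is unknown here. The next of the combined peaks found in neither replicate were X 7686729 to 7687200 (q = 5.28e-14, rank 130) and V 13854281 to 13854679 (q = 5.37e-07, rank 717).

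The block at V 20744248 to 20779152 had an outline that a biologist would want to follow up. Its covered share was 2.216 times that of the fullest other window, with an abrupt fall to 4.27% and 0% in the flanks, and the flanks held 14 and 6 replicate 1 peaks against 43 in the block. Extra copies of the transgene, which carries pha-4, a gene of chromosome V, may produce such an outline. The block was singled out as the cluster around the combined peak of lowest q. A cluster ends where 5 kb or more separates peaks, so part of the fall beside it is built in. These values therefore do not test for extra copies of the transgene. Dense binding at a native locus would also give the 78.5% covered, because native and inserted copies share their coordinates, so these cannot be told apart, and whether the block holds pha-4 was not checked for want of WS220 gene positions. Joining of neighbouring calls also stays open: the 43 replicate 1 peaks were fewer than the 45 in another window, while the 50 of replicate 2 exceeded the 37 of any other.

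The contrast between chromosomes I and V in the combined list was not found in the replicates. Combined peaks were found in both replicates less often on V than on I, 78.8% against 94.8%. Joining of peaks on I into fewer regions is argued against, because 43.2% of high-ranked replicate 1 peaks on I were overlapped by a combined peak of any width, against 92.4% on V. The replicates' own densities ran against more PHA-4 binding on V than on I. Their V to I ratio was 0.662 in replicate 1 and 0.624 in replicate 2. These ratios cannot decide the question, because the replicate and combined lists name different callers. Nothing here shows which list is nearer to the binding. A difference between chromosomes in how the combined list or the replicate lists were called stays open as a candidate explanation. At matched rank and position along the chromosome, recovery was lower on I than on V in 47 of 54 classes. Intervals were apart in 37 classes. In the 7 that were not lower on I, all within ranks 1 to 500, recovery was 100% on both. Since recovery already differed over whole chromosomes, most classes were bound to lean this way. The classes therefore show only that the difference was not confined to a single stretch or range of ranks. How the lists were called is not recorded in the sources used here.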
